A study of Mus musculus with 10 samples.

How the data were processed

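Messenger RNA levels were measured by RNA sequencing in SMB56, a spontaneous medulloblastoma line from a Ptch heterozygous mouse grown as neurospheres, and in SMB56-shSufu, the same line carrying a short hairpin RNA against Sufu. SMB56 cells had received DMSO, 0.1 µM THZ1 or 1 µM GDC-0449, and SMB56-shSufu cells DMSO or 0.1 µM THZ1, each for 8 hours. That gives 5 groups of 2 libraries, 10 in all. THZ1 is a covalent inhibitor of CDK7, and GDC-0449 (vismodegib) inhibits SMO. Per the labels' protocols, total RNA was extracted after Trizol lysis and made into libraries with an Illumina TruSeq RNA kit. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

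The authors deposited 3 tables, for THZ1 in SMB56, GDC-0449 in SMB56 and THZ1 in SMB56-shSufu. Each holds values per gene for 4 libraries that were taken as raw read counts. The headers call them counts in the SMB56 tables and give only treatment and number in the SMB56-shSufu table. Each also holds FPKM values that the authors computed for those libraries. The authors' own log2 fold change, p-value and adjusted p-value stand beside them in the deposited tables. The submitters' processing notes name STAR 2.5.3a, Cufflinks 2.2.1, DESeq2 1.20.0 and the genome build hg19, without saying which step used which. The build named is human while the gene identifiers are mouse Ensembl IDs, so genes were used by ID and symbol and no coordinates were taken. Whether counting used strand is not given in the sources used here. Columns name the treatment and a number, and the line follows from the table.

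The tables differ in which genes they hold. The SMB56 THZ1 table has 10007 genes, of which all but 8 have the authors' adjusted p-value under 0.05 in the deposited column, so it was selected on the outcome. The GDC-0449 table has 10008 genes with a mean count of at least 79.5, and the SMB56-shSufu table has 12057 genes, each with an FPKM above 1 in at least 1 library. The SMB56 DMSO counts were identical in both tables that hold them (0 differed). A total of 7244 genes stand in all 3 tables, 7417 in both SMB56 tables, 8204 in both THZ1 tables and 9719 in the GDC-0449 and SMB56-shSufu tables. Of the GDC-0449 table's genes, 2591 are absent from the SMB56 THZ1 table. The deposited folds were DMSO over treated in both SMB56 tables and treated over DMSO in the other, as checked against the counts, and were brought to treated over DMSO. Gene names that a spreadsheet had turned into dates or left blank (20, 21 and 19 in the SMB56 THZ1, GDC-0449 and SMB56-shSufu tables) were looked up by gene ID, which gave 14, 17 and 18 of them.

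Total counts per library were 10614268 to 13170421 in the SMB56 THZ1 table, 13131292 to 14986389 in the GDC-0449 table and 30100041 to 33254885 in the SMB56-shSufu table. A chi-square comparison of the 2 libraries of a group gave 1.86 per gene for SMB56 DMSO, 1.82 for GDC-0449 and 3.59 for SMB56 THZ1. It gave 62.7 for SMB56-shSufu DMSO and 26.4 for SMB56-shSufu THZ1, so no pair held the same counts. This chi-square grows with depth, so it does not by itself compare the spread of the lines. In fits of each comparison's own groups, the common biological coefficient of variation was 13.3% for THZ1 in SMB56-shSufu. It was 3.02% for THZ1 and 2.27% for GDC-0449 in SMB56, so the SMB56-shSufu libraries varied more. Cell line cannot be told apart from table, depth and sequencing in any comparison across the lines.

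The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited counts of the 7244 genes in all 3 tables. All 10 libraries were fitted together with 1 coefficient per group, TMM normalization and the filterByExpr filter, leaving 5 residual degrees of freedom and a common biological coefficient of variation of 8.62%. This fit was fixed before the data were examined. Fits of each comparison's own groups were used in its place for a time, after both sets of counts had been seen, and were then returned to the role of an alternative. Every one of the 7244 genes passed the filter. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 6 comparisons were THZ1 and GDC-0449 against DMSO in SMB56, THZ1 against DMSO in SMB56-shSufu, the difference of the THZ1 effects between the lines, the lines under DMSO, and THZ1 against GDC-0449 in SMB56. Levels are TMM-normalized CPM, given as mean ± SD over 2 libraries, and log2 fold changes are given ± their standard error. No spike-in was used, so levels and folds are relative to the other genes.

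The genes named were set by rule. Gli1, Ptch1, Hhip, Mycn, Ccnd1, Sufu, Smo and Cdk7 were always to be named. For each treatment and for the lines under DMSO, the rule took the 8 higher and 8 lower genes of largest fold that were called, had a mean CPM of at least 5 and had both libraries of a group outside the range of the other. Unnamed gene models and pseudogenes were left out. For the difference of THZ1 effects it took 5 each way without the range condition. For each gene list it allowed up to 4 members with the smallest p in the majority direction and 1 of the opposite direction, or up to 2 where no member was called. Hhip was not analysed here, and a few genes that the rule takes, tested and counted with the rest, are not reported by name. Ccnd1 and Smo stand in the GDC-0449 and SMB56-shSufu tables alone, so their values come from fits of a comparison's own groups.

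A total of 26 gene lists were fixed before the data were examined, as were the naming rule and all alternatives except those said to be added. They covered hedgehog targets, hedgehog pathway components, mitosis, DNA replication and E2F, transcription CDKs and TFIIH, DNA damage repair (homologous recombination and Fanconi), immediate early genes, short-lived survival genes, p53 targets, the unfolded protein and integrated stress response, heat shock, cholesterol synthesis, hypoxia and glycolysis, granule neuron progenitor, neuronal differentiation, neural stem and glia, cytosolic ribosomal proteins, mitochondrially encoded genes, zinc finger (Zfp) genes, nuclear-encoded OXPHOS and the proteasome. These 21 were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry were alternatives. The lists for interferon response, microglia and macrophage, fibroblast and pericyte, endothelium, and replication-dependent histones had 2, 0, 2, 0 and 1 members among the 7244 genes, too few to test.

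Also fixed in advance were repeats with RLE and upper-quartile factors, library size alone, scaling by the summed counts of the 12 mitochondrially encoded genes or of the 71 ribosomal protein genes, other low-count filters, DESeq2 1.42.0, limma-voom, and fits of a comparison's own groups. These repeats also took in limma on the deposited FPKM with pseudocounts of 1 and 0.1, a replicate block, stricter thresholds and leaving out each library in turn. Added after seeing the data were the size factors implied by the authors' deposited folds, limma-voom with quality weights by line, adjustment over the 20366 tests implied by the authors' p-values, and a fit without ribosomal RNA-like and mitochondrial genes. Other scalings moved the median of all genes from its TMM value as follows. For THZ1 in SMB56 the shift was 0.15 with RLE, -0.31 with upper-quartile factors, -0.35 with the authors' factors, -0.61 with library size, -0.94 with ribosomal protein and -1.51 with mitochondrial scaling, and -0.25 in the own-groups fit. For THZ1 in SMB56-shSufu it was -0.33, -0.23, -0.54, -0.28 and -1.43 with upper-quartile, authors', library size, ribosomal protein and mitochondrial scaling, and -0.10 in the own-groups fit. For GDC-0449 it was -0.12 with mitochondrial scaling, and for the lines under DMSO -1.34 with mitochondrial and -0.17 with ribosomal protein scaling. For the difference of THZ1 effects it was 0.12 with the authors' factors and 0.67 with ribosomal protein scaling. For THZ1 against GDC-0449 it was 0.14, -0.34, -0.62, -0.33, -1.39 and -0.96 with RLE, upper-quartile, library size, authors', mitochondrial and ribosomal protein scaling. All other shifts were smaller than 0.1.

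The test was tried on simulated counts for the 7244 genes with 200 genes changed by 1.2, 1.5 or 2 fold, up or down at random. With so few genes changed, the simulation did not test the normalization where most genes change, as was called with THZ1. At 2 fold it recovered 95.5% of the changed genes for THZ1 in SMB56, 100% for GDC-0449, 95.5% for THZ1 in SMB56-shSufu, 66.7% for the difference of THZ1 effects, 97.0% for the lines and 97.0% for THZ1 against GDC-0449. At 1.5 fold the shares were 59.7%, 68.7%, 71.6%, 26.9%, 64.2% and 61.2%, and at 1.2 fold 0%, 0%, 19.4%, 1.49%, 5.97% and 0%. Unchanged genes called numbered 130 of 7044 for THZ1 in SMB56-shSufu, 13 for the lines, 4 for the difference and 0 for each of the other 3. The pooled spread thus made tests within SMB56 conservative and the test of THZ1 in SMB56-shSufu too lenient. In the latter, the 130 unchanged genes called stood beside 13, 48 and 63 changed genes recovered at 1.2, 1.5 and 2 fold. There, 18.1% of unchanged genes had an unadjusted p under 0.05. In the GDC-0449 simulation that share was 0.0994%.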

Results

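After 8 hours, THZ1 changed 5883 of 7244 genes in SMB56 medulloblastoma cells and 5938 in SMB56-shSufu cells. All 7244 genes come through a table selected on the THZ1 outcome in SMB56, so such shares do not hold for all genes. GDC-0449 changed 145 of 7244 in SMB56, where the fit of its own groups called 2758 of the same genes, and the count was 35 without SMB56 DMSO replicate 1 and 941 without SMB56-shSufu DMSO replicate 1. Gli1, a transcription factor and target of the hedgehog pathway, fell with either compound, whereas the hedgehog receptor Ptch1 fell with GDC-0449 and rose with THZ1 under TMM scaling. Mitochondrially encoded genes made up 3.01% of the counts in both SMB56 DMSO libraries and 3.38% and 3.21% with GDC-0449, measured over the GDC-0449 table. Over the SMB56 THZ1 table the share was 3.42% in both DMSO libraries and 6.84% and 5.96% with THZ1. In SMB56-shSufu it was 5.83% and 8.18% with DMSO and 12.9% in both libraries with THZ1. SMB56-shSufu libraries held 30100041 to 33254885 counts and SMB56 libraries 10614268 to 14986389.

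Sufu, the negative regulator that binds GLI proteins and the target of the short hairpin RNA, stood at 72.3 and 67.6 CPM in the SMB56 DMSO libraries and at 23.7 and 24.7 in the SMB56-shSufu DMSO libraries. In SMB56 its level was 151 and 159 with THZ1 and 59.5 and 56.5 with GDC-0449. In SMB56-shSufu it was 115 and 108 with THZ1. Under DMSO it was 2.89-fold lower in SMB56-shSufu than in SMB56 (log2 fold change -1.53 ± 0.08, edgeR adjusted p 4.0e-07, n = 2). THZ1 raised Sufu 2.22-fold in SMB56 (1.15 ± 0.08, edgeR adjusted p 2.7e-07; -0.36, the opposite direction, under mitochondrial scaling) and 4.61-fold in SMB56-shSufu (2.204 ± 0.08, edgeR adjusted p 7.0e-09). With GDC-0449 its fold was -0.27 ± 0.08 (edgeR adjusted p 0.14), and the fit of its own groups called it lower (-0.28 ± 0.06, edgeR adjusted p 0.00029). It was also called without SMB56-shSufu DMSO replicate 1 (edgeR adjusted p 0.029) or 2 (edgeR adjusted p 0.031).

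**Figure D1:**
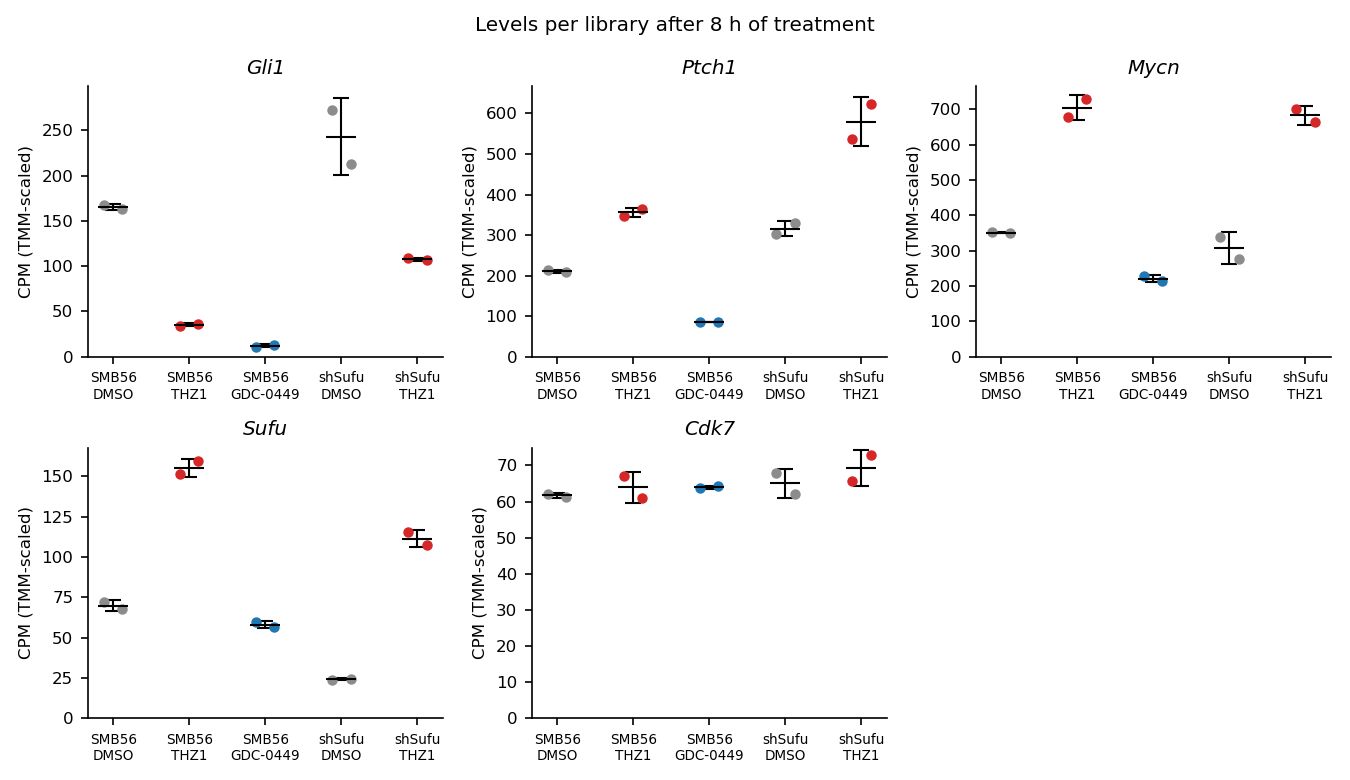
Levels of Gli1, Ptch1, Mycn, Sufu and Cdk7 in TMM-normalized CPM. Dots are libraries and bars are mean ± SD of 2 libraries per group.

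Gli1 fell 13.4-fold with GDC-0449 (log2 fold change -3.75 ± 0.13, edgeR adjusted p 7.1e-08), from 166 ± 3.2 to 12.4 ± 1.5 CPM (n = 2). The hedgehog receptor gene Ptch1 fell 2.47-fold (-1.30 ± 0.09, edgeR adjusted p 1.7e-05), and the transcription factor Mycn fell 1.59-fold (-0.67 ± 0.10, edgeR adjusted p 0.0060). Mycn lost its call without either SMB56 DMSO or either GDC-0449 library, with folds of -0.71 to -0.63. The fit of the comparison's own groups called Mycn lower (-0.67 ± 0.03, edgeR adjusted p 4.3e-16). In the fit of its own groups, Ccnd1, the G1 cyclin D1, fell (-1.58 ± 0.04, edgeR adjusted p 5.6e-24), as did Smo, the target of the compound (-0.26 ± 0.04, edgeR adjusted p 8.4e-07). Cdk7, the kinase of TFIIH, had a fold of 0.050 ± 0.09 (edgeR adjusted p 0.80).

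The lower genes of largest fold also included Hpca, a neuronal calcium sensor (-2.41 ± 0.08, edgeR adjusted p 3.2e-08), which went from 283 to 53.2 CPM. The metalloprotease gene Adamts14 (-2.33 ± 0.18, edgeR adjusted p 4.9e-05) and Tbata (-2.07 ± 0.10, edgeR adjusted p 7.3e-07) fell. Lrp8, a reelin receptor (-1.90 ± 0.19, edgeR adjusted p 0.00030), fell as well. So did Rgma, a guidance molecule (-1.66 ± 0.13, edgeR adjusted p 4.6e-05), and the protamine gene Prm1 (-1.56 ± 0.17, edgeR adjusted p 0.00057). Genes that rose did so by less. They included Igfbp5, which encodes an IGF-binding protein (0.86 ± 0.12, edgeR adjusted p 0.0034), Mybpc1 (0.81 ± 0.12, edgeR adjusted p 0.0060) and Trp53inp1 (0.74 ± 0.10, edgeR adjusted p 0.0029). Smaller rises were in Flnc (0.64, edgeR adjusted p 0.032), Fgfr4 (0.62, edgeR adjusted p 0.017), Ifi30 (0.62, edgeR adjusted p 0.036), Rasd2 (0.59, edgeR adjusted p 0.0060) and Ppfia2 (0.59, edgeR adjusted p 0.022). Each of these 8 higher genes lost its call with some SMB56 library left out (edgeR adjusted p 0.0519 to 0.309).

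Of 9 measured hedgehog targets 4 fell and 0 rose (adjusted over the list alone, 4 fell and 1 rose), with a median of -0.24 (camera adjusted p 1.8e-26, adjusted p = 0.0083 with an estimated correlation). Replication and E2F genes fell with GDC-0449, 8 of 22 and none the other way (adjusted over the list alone, 20), with a median of -0.34 (camera adjusted p 2.1e-17, adjusted p = 0.0083 with an estimated correlation). Examples are the helicase genes Mcm3 (-0.68 ± 0.10, edgeR adjusted p 0.0058) and Mcm2 (-0.58 ± 0.09, edgeR adjusted p 0.0060) and the licensing factor Cdc6 (-0.57 ± 0.09, edgeR adjusted p 0.0085). All 3, and Exo1, lost the call without either SMB56 DMSO or either GDC-0449 library (edgeR adjusted p 0.0535 to 0.161). Hedgehog pathway components had a median of -0.22 (camera adjusted p 0.0050, adjusted p = 0.12 with an estimated correlation), and 1 of 10, the transcription factor Gli2 (-0.72 ± 0.15, edgeR adjusted p 0.036), fell (adjusted over the list alone, 4). Gli2 lost its call without any 1 of the 6 SMB56 libraries (edgeR adjusted p 0.0865 to 0.330). Repair genes had a median of -0.18 (camera adjusted p 0.0098, adjusted p = 0.61 with an estimated correlation), and 1 of 16, the nuclease gene Exo1 (-0.47 ± 0.07, edgeR adjusted p 0.0093), fell. The mitosis list had 0 called members and was not called (camera adjusted p 0.36).

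Granule neuron progenitor genes had a median of 0.30 (camera adjusted p 4.1e-06, adjusted p = 0.085 with an estimated correlation), with 2 of 11 higher (adjusted over the list alone, 7). These were Meis1 (0.44 ± 0.08, edgeR adjusted p 0.023) and Barhl1 (0.44 ± 0.09, edgeR adjusted p 0.030), both transcription factors of that lineage. Both lost the call without any 1 of the 6 SMB56 libraries (edgeR adjusted p 0.0611 to 0.293). Neuronal differentiation genes had a median of 0.34 (camera adjusted p 0.0014, adjusted p = 0.22 with an estimated correlation) with 0 of 11 called (adjusted over the list alone, 5). Neurod6 stood at 0.71 ± 0.20 (edgeR adjusted p 0.11) and Cntn2 at 0.39 ± 0.12 (edgeR adjusted p 0.16). Mitochondrially encoded genes had a median of 0.18 (camera adjusted p 0.00026, adjusted p = 0.41 with an estimated correlation), with 0 of 12 called (adjusted over the list alone, 4). Zfp genes had a median of 0.11, which was below 0 under mitochondrial scaling (camera adjusted p 0.0024, adjusted p = 0.53 with an estimated correlation), with 0 called. Hypoxia and glycolysis genes had a median of -0.17 (camera adjusted p 0.013, adjusted p = 0.41 with an estimated correlation), again with 0 called. Among lists without a camera call, the p53 target list had 2 higher members (adjusted over the list alone, 4 higher and 2 lower), Trp53inp1 and Ddit4 (0.43 ± 0.09, edgeR adjusted p 0.026; camera adjusted p 0.12 for the list). Ddit4 lost its call without either SMB56 DMSO or either GDC-0449 library (edgeR adjusted p 0.157 to 0.327). Neural stem and glia had 1 lower member, Sox9 (-1.38 ± 0.11, edgeR adjusted p 7.1e-05; camera adjusted p 0.069 for the list).

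The other lists for GDC-0449 gave no camera call. The unfolded protein and integrated stress response had 1 higher member (adjusted over the list alone, 1 higher and 1 lower; camera adjusted p 0.48). Immediate early genes had 0 (adjusted over the list alone, 2 higher and 1 lower; camera adjusted p 0.36), and short-lived survival genes 0 (adjusted over the list alone, 1 higher; camera adjusted p 0.33). Heat shock (camera adjusted p 0.30), cholesterol synthesis (camera adjusted p 0.71), transcription CDKs and TFIIH (camera adjusted p 0.86), ribosomal proteins (camera adjusted p 0.86), OXPHOS (camera adjusted p 0.86) and proteasome (camera adjusted p 0.36) had 0 called members each.

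GDC-0449 changed 145 of 7244 genes, 38 higher and 107 lower, of which 35 by at least 2-fold, all lower. The fit of its own groups, which changes both the genes and the libraries used, called 3633 of 10008 genes (1755 higher and 1878 lower), 2758 of them among the 7244. The split was 0 higher and 42 lower under mitochondrial scaling, 4 and 38 under ribosomal protein scaling, and 6 and 45 on FPKM. The count moved with the libraries used. It was 35 and 50 without SMB56 DMSO replicate 1 and 2, 90 without either SMB56 THZ1 library, and 38 and 35 without GDC-0449 replicate 1 and 2. It was 941 and 926 without SMB56-shSufu DMSO replicate 1 and 2, and 173 without either SMB56-shSufu THZ1 library.

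Knstrn, a kinetochore component, fell with THZ1 in SMB56 (-2.08 ± 0.09, edgeR adjusted p 1.1e-08, n = 2), as did Top2a, a topoisomerase (-1.29 ± 0.09, edgeR adjusted p 2.1e-07), and Mcm10, which acts in replication initiation (-1.96 ± 0.10, edgeR adjusted p 2.9e-08). Polr2a, the largest subunit of RNA polymerase II, rose (2.74 ± 0.10, edgeR adjusted p 6.2e-09), and so did the elongation factor gene Supt5 (1.81 ± 0.07, edgeR adjusted p 9.7e-09). The hedgehog genes divided. Gli1 fell 4.66-fold (-2.22 ± 0.12, edgeR adjusted p 6.2e-08) and Gli2 fell (-1.59 ± 0.17, edgeR adjusted p 4.8e-06). Ptch1 rose 1.69-fold with TMM (0.76 ± 0.09, edgeR adjusted p 1.0e-05; -0.75 under mitochondrial scaling, -0.18 under ribosomal protein scaling, -0.37 on FPKM, and 0.14, not called, with library size). Mycn rose (1.00 ± 0.10, edgeR adjusted p 3.3e-06; -0.51 under mitochondrial scaling), and Foxm1, a mitotic transcription factor, fell (-1.51 ± 0.12, edgeR adjusted p 6.5e-07). Cdk7, which encodes the kinase THZ1 binds, stood at 61.8 CPM with DMSO and 64.0 with THZ1 (0.051 ± 0.09, edgeR adjusted p 0.62) under TMM. It was called lower with library size (-0.56), upper-quartile (-0.26), authors' (-0.30), mitochondrial (-1.47) and ribosomal protein scaling (-0.89), in the fit of its own groups (-0.20) and on FPKM (-0.77).

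The genes with the largest rise in counts were Lars2, the mitochondrial leucyl-tRNA synthetase (4.52 ± 0.14, edgeR adjusted p 4.8e-09), from 259 to 5960 CPM, and Lag3, an immune checkpoint receptor (4.10 ± 0.14, edgeR adjusted p 5.1e-09), from 7.43 to 127 CPM. Lars2 was treated as one of the ribosomal RNA-like genes, and which RNA its reads came from remained open. Tob1, an antiproliferative protein of the BTG/TOB family (3.42 ± 0.15, edgeR adjusted p 1.3e-08), the kinases Map3k2 (3.36 ± 0.11) and Pkn3 (3.25 ± 0.17), Ier5l (3.21 ± 0.21), Zcchc3 (3.14 ± 0.11) and Gpr62 (3.04 ± 0.13) followed. The gene model Gm26917, which the naming rule passes over, was higher still (8.86 ± 0.36, edgeR adjusted p 1.1e-08) and took 5.399% and 5.51% of the counts with THZ1, against 0.0174% and 0.0186% with DMSO. The genes lowered most were Cldn2, a claudin of tight junctions (-4.31 ± 0.35, edgeR adjusted p 6.6e-07), Pdzrn4 (-3.95 ± 0.12, edgeR adjusted p 4.8e-09), from 221 to 14.3 CPM, and Gnb1l (-3.85 ± 0.31). Nadsyn1, an NAD synthetase (-3.50 ± 0.37), Tab1, which binds the kinase TAK1 (-3.39 ± 0.18), Tti1, which stabilises PI3K-related kinases (-3.37 ± 0.09, edgeR adjusted p 4.8e-09), Fgd3 (-3.36 ± 0.21) and Ccdc14 (-3.08 ± 0.18) also fell.

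By list, 14 of 21 mitosis genes fell and 1, Aurka (0.62 ± 0.14, edgeR adjusted p 0.0017; below 0 on FPKM and under mitochondrial or ribosomal protein scaling), rose. The list median was -0.46 (camera adjusted p 0.018, adjusted p = 0.61 with an estimated correlation). Replication and E2F genes fell, 18 of 22 with 3 rising (median -0.97, camera adjusted p 0.00033, adjusted p = 0.32 with an estimated correlation). They include the thymidine kinase gene Tk1 (-1.90 ± 0.11, edgeR adjusted p 9.3e-08), while Mcm7 rose with TMM (0.60 ± 0.08, edgeR adjusted p 2.5e-05; below 0 on FPKM and with library size, mitochondrial or ribosomal protein scaling). Repair genes fell, 14 of 16 with 0 rising (median -0.77, camera adjusted p 0.0079, adjusted p = 0.61 with an estimated correlation), among them Brca2 (-1.77 ± 0.13, edgeR adjusted p 3.2e-07), Fancd2 (-1.25 ± 0.09) and Exo1 (-1.24 ± 0.08). Of the 15 genes of transcription CDKs and TFIIH 8 rose and 2 fell, with a median of 0.64 that was below 0 under mitochondrial and ribosomal protein scaling (camera adjusted p 0.031, adjusted p = 0.47 with an estimated correlation). The camera call for mitosis was lost under mitochondrial scaling (camera adjusted p 0.0567), and that for TFIIH with library size (0.0721) and mitochondrial scaling (0.103).

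Granule neuron progenitor genes rose, 8 of 11 with 2 falling (median 1.08, below 0 under mitochondrial scaling; camera adjusted p 0.013, adjusted p = 0.51 with an estimated correlation). Atoh1, a transcription factor of these progenitors (1.42 ± 0.08, edgeR adjusted p 4.6e-08; below 0 under mitochondrial scaling), Zic1 (1.49 ± 0.08; below 0 under mitochondrial scaling) and Zic4 (2.03 ± 0.14) rose, and Barhl2 fell (-1.04 ± 0.12, edgeR adjusted p 1.3e-05). Hypoxia and glycolysis genes rose, 9 of 12 with 1 falling (median 0.87, below 0 under mitochondrial and ribosomal protein scaling; camera adjusted p 0.031, adjusted p = 0.61 with an estimated correlation). The growth factor gene Vegfa stood at 1.36 ± 0.08 (edgeR adjusted p 7.9e-08; below 0 under mitochondrial scaling) and the pyruvate kinase gene Pkm at 1.29 ± 0.08 (below 0 under mitochondrial scaling). Ribosomal protein genes rose, 69 of 71 with 0 falling (median 0.89, camera adjusted p 1.2e-08, adjusted p = 0.61 with an estimated correlation). Their median was below 0 under mitochondrial scaling, and also under ribosomal protein scaling, which is set by these same genes. Rps15a (1.27 ± 0.07, edgeR adjusted p 7.9e-08; below 0 on FPKM and under mitochondrial scaling) and Rplp0 (1.504 ± 0.10; below 0 under mitochondrial scaling) are examples, though reads of such genes can fall on near-identical pseudogenes, which was not tested, so their values are uncertain. All 12 mitochondrially encoded genes rose (median 1.62, camera adjusted p 0.0018, adjusted p = 0.61 with an estimated correlation), such as mt-Nd4 (1.62 ± 0.14, edgeR adjusted p 1.1e-06) and mt-Co1 (1.58 ± 0.14). Of 191 Zfp genes 122 fell and 41 rose (median -0.56, camera adjusted p 0.032, adjusted p = 0.66 with an estimated correlation; lost with library size, camera adjusted p 0.0913). Zfp239 fell (-2.49 ± 0.13, edgeR adjusted p 3.6e-08) and Zfp36l2, an RNA-binding protein of mRNA decay, rose (2.96 ± 0.08, edgeR adjusted p 4.8e-09).

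The other 12 lists were not called for THZ1 in SMB56, although they had called members. Immediate early genes had 5 higher and 1 lower of 6 (median 1.21, below 0 under mitochondrial scaling; camera adjusted p 0.095), with Myc at 1.49 ± 0.09 (edgeR adjusted p 1.2e-07; below 0 under mitochondrial scaling) and Klf6 at 2.12 ± 0.17. The p53 targets had 7 higher and 3 lower of 11 (median 1.11, below 0 under mitochondrial scaling; camera adjusted p 0.055), with the apoptosis gene Bbc3 at 2.68 ± 0.16 and Cdkn1a, which encodes p21, at 2.12 ± 0.18. OXPHOS genes had 24 higher and 12 lower (median 0.58, below 0 with library size, mitochondrial or ribosomal protein scaling; camera adjusted p 0.085). Hedgehog targets had 3 higher and 5 lower (median -0.62, camera adjusted p 0.60) and pathway components 3 and 7 (-0.69, camera adjusted p 0.40). The counts were for neural stem and glia 2 and 4 (-0.62, camera adjusted p 0.51), for neuronal differentiation 2 and 5 (-0.35, camera adjusted p 0.51) and for cholesterol synthesis 2 and 5 (-0.30, camera adjusted p 0.58). Heat shock had 4 and 3 (0.41, below 0 with library size, mitochondrial or ribosomal protein scaling; camera adjusted p 0.65), and the stress response 5 and 3 (0.11, below 0 under every scaling but RLE; camera adjusted p 0.49). Short-lived survival genes had 1 higher and 2 lower, with a median of -0.29 but a mean of 0.07 (camera adjusted p 1.0, direction down; fry gave up). The proteasome had 8 and 11, with a median of -0.14 that was above 0 with RLE and a camera direction of up (camera adjusted p 1.0). Counts adjusted over the list alone were the same for all 21 lists.

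THZ1 changed 5883 of 7244 genes in SMB56, 2571 higher and 3312 lower, of which 2699 by at least 2-fold (1415 higher and 1284 lower). The fit of its own groups called 9813 of 9863 (4373 higher and 5440 lower). The split between higher and lower was relative: it was 1741 and 4683 with library size, 764 and 4843 with ribosomal protein scaling, 171 and 5994 with mitochondrial scaling, and 1054 and 4752 on FPKM. The authors' own zero lay 0.350 from the zero used here, in a table already selected on this outcome.

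**Figure D2:**
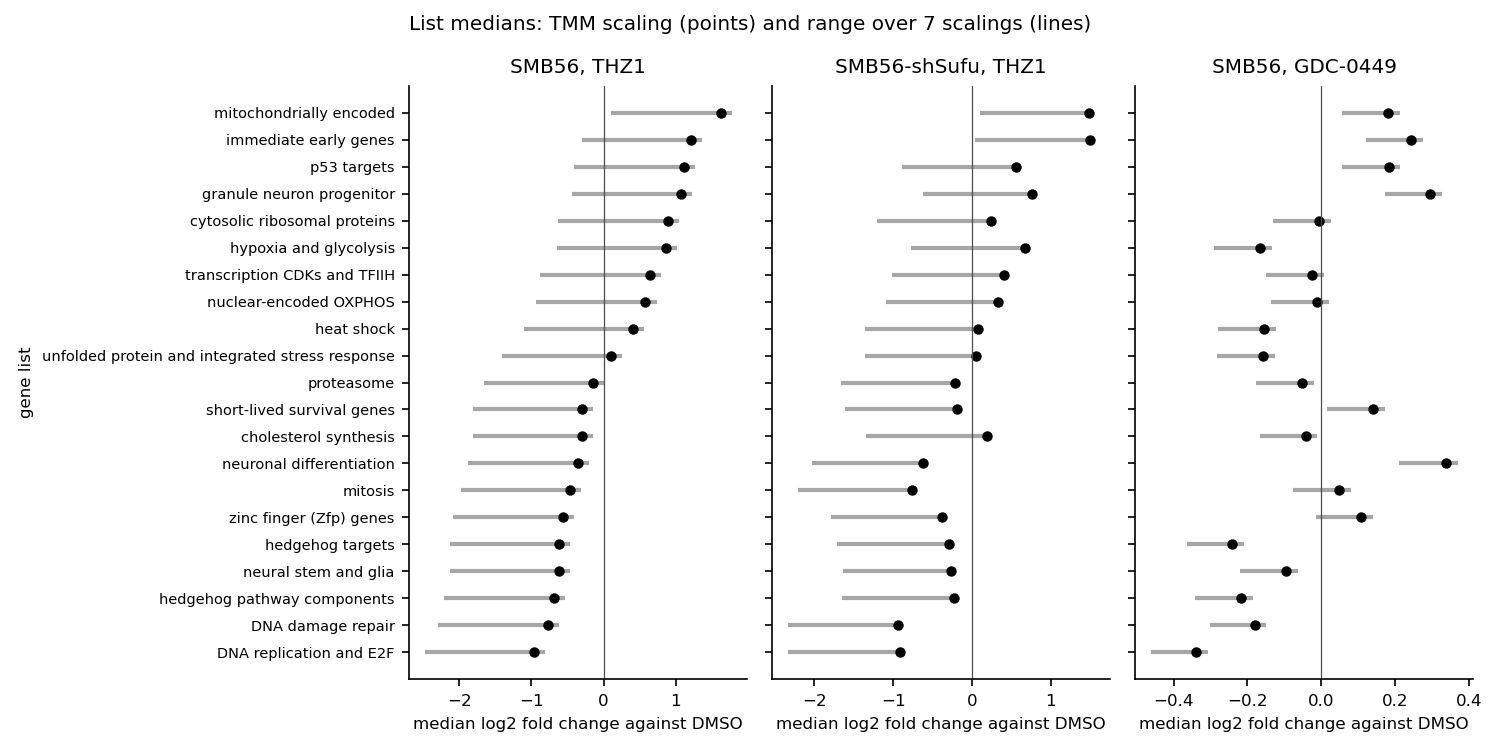
Median log2 fold change of the 21 lists for THZ1 in SMB56, THZ1 in SMB56-shSufu and GDC-0449 in SMB56. Points use TMM, and lines span 7 scalings. A line crossing 0 marks a list whose direction turns with scaling, such as hypoxia and glycolysis with THZ1 in SMB56 under mitochondrial and ribosomal protein scaling. For ribosomal proteins and mitochondrially encoded genes, scaling by the list's own summed counts holds that sum level by construction.

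THZ1 in SMB56-shSufu lowered Gli1 2.25-fold (-1.17 ± 0.11, edgeR adjusted p 2.2e-06, n = 2), from 243 ± 42 to 108 ± 1.7 CPM. It lowered Gli2 (-1.04 ± 0.15, edgeR adjusted p 4.9e-05) and Foxm1 (-0.91 ± 0.11, edgeR adjusted p 1.9e-05). Ptch1 rose 1.83-fold (0.87 ± 0.09, edgeR adjusted p 2.9e-06; -0.55 under mitochondrial scaling) and Mycn 2.22-fold (1.15 ± 0.10, edgeR adjusted p 1.1e-06; -0.31 under mitochondrial scaling). In the fit of its own groups Ccnd1 rose (1.36 ± 0.18, edgeR adjusted p 3.0e-05) and Smo rose (0.42 ± 0.15, edgeR adjusted p 0.022). Neither was repeated under another scaling. The median of all genes shifted from TMM by -0.54 with library size and -1.43 with mitochondrial scaling, against -0.10 with own groups. Neither rise is therefore shown to hold under those scalings. Cdk7 had a fold of 0.091 ± 0.09 (edgeR adjusted p 0.35) under TMM, and was called lower with library size (-0.45), upper-quartile (-0.23) and mitochondrial scaling (-1.35) and on FPKM (-0.55).

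Lars2, with the source of its reads open as above, again had the largest rise among named genes (6.80 ± 0.16, edgeR adjusted p 1.2e-09), from 34.7 to 3872 CPM. It was followed by Ier5l (3.99 ± 0.22), the RNA-binding protein gene Rbm12 (3.92 ± 0.12, edgeR adjusted p 3.4e-09), the repressor gene Hic2 (3.56 ± 0.12), Tob1 (3.51 ± 0.15), Lag3 (3.37 ± 0.13) and Gpr62 (3.01 ± 0.13). Gm26917 rose by 8.99 ± 0.36 (edgeR adjusted p 9.9e-09), from 0.00694% and 0.00389% of the counts to 1.48% and 2.37%. The genes lowered most were Bbs12, a Bardet-Biedl syndrome gene (-3.52 ± 0.26), Pdzrn4 (-3.46 ± 0.11, edgeR adjusted p 4.4e-09), the nucleoside diphosphate kinase gene Nme6 (-3.30 ± 0.24) and the delta tubulin gene Tubd1 (-3.18 ± 0.26). Btbd17 (-2.97 ± 0.12), Cldn2 (-2.92 ± 0.20, edgeR adjusted p 1.7e-07), the tRNA guanylyltransferase gene Thg1l (-2.91 ± 0.17) and Dscc1, which acts in sister chromatid cohesion (-2.87 ± 0.17, edgeR adjusted p 6.3e-08), fell too.

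In this line 17 of 21 mitosis genes fell and 1, Mki67 (0.55 ± 0.10, edgeR adjusted p 0.00039; below 0 on FPKM and under mitochondrial scaling), rose, with a list median of -0.76 (camera adjusted p 0.0031, adjusted p = 0.67 with an estimated correlation). Knstrn (-1.82 ± 0.08, edgeR adjusted p 1.1e-08) and Top2a (-1.58 ± 0.09) were among them. Replication and E2F genes fell, 17 of 22 with 2 rising (median -0.91, camera adjusted p 0.00058, adjusted p = 0.24 with an estimated correlation), such as Mcm10 (-2.14 ± 0.09, edgeR adjusted p 1.2e-08) and the cyclin gene Ccne2 (-1.92 ± 0.10). Repair genes fell, 13 of 16 with 1 rising (median -0.94, camera adjusted p 0.0040, adjusted p = 0.67 with an estimated correlation), such as Brca2 (-1.76 ± 0.11, edgeR adjusted p 1.2e-07), Rad51c (-2.23 ± 0.15) and Fancd2 (-1.26 ± 0.08). Immediate early genes rose, 5 of 6 with 1 falling (median 1.5, camera adjusted p 0.020, adjusted p = 0.67 with an estimated correlation). Myc (1.68 ± 0.09, edgeR adjusted p 3.4e-08), Klf6 (2.45 ± 0.15) and Jun (2.14 ± 0.17), all transcription factors, rose, and the antiproliferative gene Btg2 fell (-0.46 ± 0.08, edgeR adjusted p 0.00019). Granule neuron progenitor genes rose, 8 of 11 with 2 falling (median 0.77, below 0 under mitochondrial scaling; camera adjusted p 0.0061, adjusted p = 0.67 with an estimated correlation). Atoh1 (2.08 ± 0.08, edgeR adjusted p 6.9e-09) and Sox4 (1.75 ± 0.09, edgeR adjusted p 2.5e-08) rose and Meis1 fell (-0.62 ± 0.09, edgeR adjusted p 4.1e-05). All 12 mitochondrially encoded genes rose (median 1.49, camera adjusted p 0.010, adjusted p = 0.67 with an estimated correlation), with mt-Nd4 at 1.57 ± 0.14 (edgeR adjusted p 1.3e-06).

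The remaining 15 lists were not called in SMB56-shSufu. Transcription CDKs and TFIIH had 8 higher and 5 lower (median 0.41, below 0 with library size and mitochondrial scaling; camera adjusted p 0.27), among them Supt5 (1.41 ± 0.07; below 0 under mitochondrial scaling) and Polr2a (1.78 ± 0.09, edgeR adjusted p 3.4e-08). Ribosomal proteins had 35 higher and 6 lower (median 0.24, camera adjusted p 0.22), and 34 and 4 adjusted over the list alone. Their median was below 0 with upper-quartile, library size or mitochondrial scaling, and also with ribosomal protein scaling, which is set by these same genes. Zfp genes had 51 higher and 110 lower (median -0.37, camera adjusted p 0.21). OXPHOS had 25 and 12 (0.33, below 0 with library size and mitochondrial scaling; camera adjusted p 0.22), hypoxia and glycolysis 9 and 2 (0.67, below 0 under mitochondrial scaling; camera adjusted p 0.11) and p53 targets 7 and 2 (0.56, below 0 under mitochondrial scaling; camera adjusted p 0.22). Hedgehog targets had 3 higher and 6 lower with a median of -0.29, where fry gave up (camera adjusted p 0.98). Pathway components had 3 and 5 (adjusted over the list alone, 4 and 5) with a median of -0.23 and a camera direction of up (camera adjusted p 0.98). Survival genes had 1 and 2 (camera adjusted p 0.71), the stress response 6 and 5 (camera adjusted p 0.54), heat shock 4 and 3 (camera adjusted p 0.98) and cholesterol synthesis 6 and 2 (camera adjusted p 0.78). Neuronal differentiation had 3 and 7 (camera adjusted p 0.71), neural stem and glia 2 and 3 (camera adjusted p 0.98, fry up), and the proteasome 8 and 10 (camera adjusted p 0.61). Counts adjusted over the list alone were the same for all other lists.

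THZ1 changed 5938 of 7244 genes in SMB56-shSufu, 2774 higher and 3164 lower, of which 2438 by at least 2-fold (1222 higher and 1216 lower). The fit of its own groups called 7355 of 11886 (3511 higher and 3844 lower), 5270 of them among the 7244. Its common biological coefficient of variation was 13.3%, against 8.62% in the main fit, so the main count is likely too high. These genes come through the table selected on the THZ1 outcome in SMB56. The split was 2099 higher and 4009 lower with upper-quartile factors, 1641 and 4512 with library size, 1996 and 3677 with ribosomal protein scaling, 183 and 5992 with mitochondrial scaling, and 1061 and 4808 on FPKM.

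THZ1 folds in the lines went together over 7244 genes (Pearson r 0.902, Spearman rho 0.898), and 88.1% of genes had the same sign. Both lines had 2342 genes higher (985 expected by independence) and 2717 lower (1447 expected), and 16 and 99 were called in opposite directions (1123 and 1268 expected). Genes are not independent, so the expected numbers give only a scale. The genes also come through a table selected on the SMB56 THZ1 outcome, so neither the correlation nor the share of equal sign holds for all genes.

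Some genes responded differently to THZ1 in SMB56-shSufu than in SMB56. Sufu rose by more in SMB56-shSufu (difference of log2 folds 1.05 ± 0.11, edgeR adjusted p 0.00054, n = 2), and Gli1 fell by less (1.05 ± 0.17, edgeR adjusted p 0.0024; not called under mitochondrial scaling). The differences for Ptch1 (0.12 ± 0.12, edgeR adjusted p 0.50), Mycn (0.15 ± 0.14, edgeR adjusted p 0.46) and Cdk7 (0.040 ± 0.13, edgeR adjusted p 0.84) did not pass. Lars2, its reads of uncertain source, rose by more (2.28 ± 0.18, edgeR adjusted p 0.00031), as did Atoh1 (0.66 ± 0.11, edgeR adjusted p 0.0025, not called under mitochondrial scaling).

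Mgat3, a glycosyltransferase gene, went from 32.4 to 109 CPM in SMB56-shSufu and from 54.8 to 55.3 in SMB56 (1.73 ± 0.16, edgeR adjusted p 0.00031). Ksr1, a scaffold of MAP kinase signalling, went from 17.7 to 23.6 and from 16.4 to 5.38 (2.03 ± 0.23, edgeR adjusted p 0.00074). Gnb1l (2.11 ± 0.40, edgeR adjusted p 0.0051) and the Nogo receptor gene Rtn4r (1.76 ± 0.43, edgeR adjusted p 0.014) also had positive differences. Pkn3 went from 10.4 to 19.5 in SMB56-shSufu and from 6.43 to 61.1 in SMB56 (-2.34 ± 0.23, edgeR adjusted p 0.00037). Pcp4, a regulator of calmodulin, was near the floor in SMB56-shSufu, at 0.907 and 0.0485 against 26.3 and 52.9 (-4.99 ± 0.57, edgeR adjusted p 0.00068). The palmitoyltransferase gene Zdhhc12 (-1.92 ± 0.27, edgeR adjusted p 0.0015), Isoc2a (-1.58 ± 0.23, edgeR adjusted p 0.0018) and Znrd1as (-1.51 ± 0.35, edgeR adjusted p 0.011) had negative differences, the last an antisense gene whose reads are uncertain. Rtn4r lost its call without either SMB56 THZ1 library or SMB56-shSufu THZ1 replicate 2 (edgeR adjusted p 0.0509 to 0.0734), and Znrd1as without SMB56 THZ1 replicate 1 (edgeR adjusted p 0.0827). Neither was called under mitochondrial scaling.

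By list, 54 of 71 ribosomal protein genes had a lower THZ1 response in SMB56-shSufu and 0 a higher response (adjusted over the list alone, 66 lower), with a median of -0.67 (camera adjusted p 3.9e-26, adjusted p = 0.65 with an estimated correlation). Rpl17 (-1.38 ± 0.16, edgeR adjusted p 0.00088) and Rps6 (-1.16 ± 0.16, edgeR adjusted p 0.0015) are examples, with the same uncertainty from pseudogenes. Of transcription CDKs and TFIIH 6 of 15 were lower and 0 higher (adjusted over the list alone, 7 and 1; median -0.28, above 0 under ribosomal protein scaling; camera adjusted p 0.033, adjusted p = 0.35 with an estimated correlation). Polr2a (-0.96 ± 0.13, edgeR adjusted p 0.0012) was lower, as was the TFIIH subunit gene Gtf2h1 (-0.93 ± 0.13, edgeR adjusted p 0.0014). That call was lost with library size (camera adjusted p 0.0530), mitochondrial scaling (0.0926) and the own-groups fit (0.0585). Hedgehog pathway components had 3 of 10 members higher and 0 lower (median 0.43, camera adjusted p 0.033, adjusted p = 0.35 with an estimated correlation): Sufu, Gpr161 (0.72 ± 0.12, edgeR adjusted p 0.0029) and Kif7 (0.71 ± 0.20, edgeR adjusted p 0.025). Under mitochondrial scaling Rps6, Polr2a, Gtf2h1, Gpr161 and Kif7 were not called. Kif7 lost its call without SMB56 DMSO replicate 2, either SMB56 THZ1 library or SMB56-shSufu THZ1 replicate 1 (edgeR adjusted p 0.0579 to 0.116). Without SMB56-shSufu DMSO replicate 1, the TFIIH (camera adjusted p 0.0511) and component calls (0.0642) were lost. The other 18 lists were not called (camera adjusted p 0.057 to 0.91). Among them, the granule neuron progenitor list had a median of 0.15 and a mean of -0.02.

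The THZ1 response differed between the lines for 1828 of 7244 genes, 996 higher and 832 lower in SMB56-shSufu, of which 228 by at least 2-fold (139 and 89). The fit of its own groups called 1504 of 8204 genes, 1361 of them among the 7244, with a common biological coefficient of variation of 9.61% against 8.62%. The split was 1295 and 632 with library size, 705 and 1234 with RLE and 686 and 1201 with DESeq2. It was 1539 and 542 with the authors' factors, 77 and 16 with mitochondrial scaling, 4527 and 23 with ribosomal protein scaling, and 627 and 294 on FPKM. The count was 892 and 876 without SMB56 DMSO replicate 1 and 2, 869 and 1013 without SMB56 THZ1 replicate 1 and 2, and 2943 and 2985 without SMB56-shSufu DMSO replicate 1 and 2. Line and sequencing cannot be separated in these differences. The lists called were 5 without SMB56 DMSO replicate 2, 6 without SMB56-shSufu DMSO replicate 2 and 5 without SMB56-shSufu THZ1 replicate 1, against 3.

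**Figure D3:**
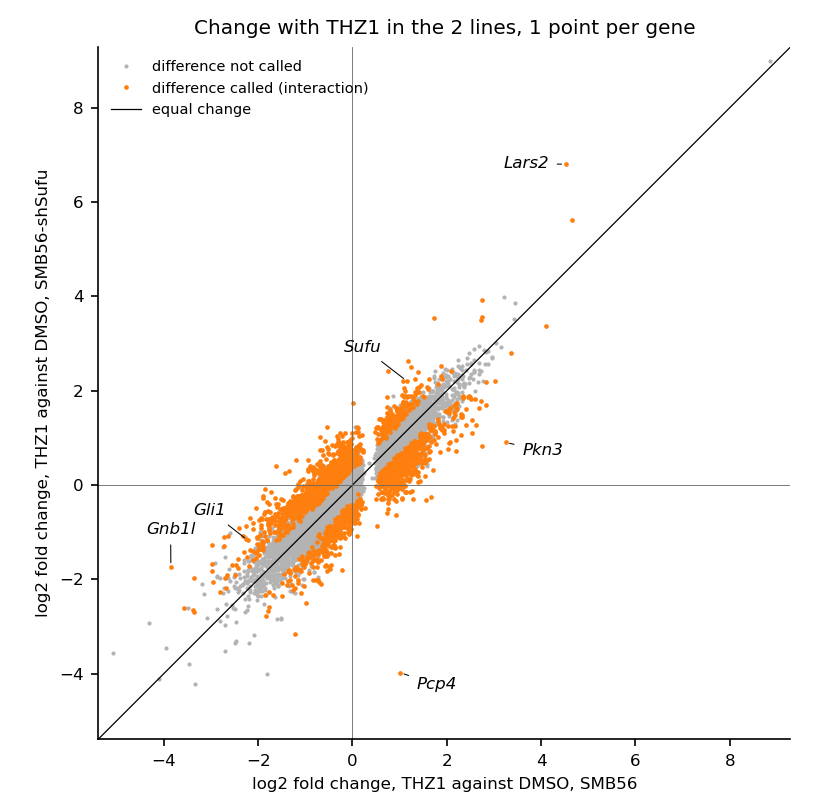
Log2 fold change with THZ1 in SMB56 and in SMB56-shSufu, with genes whose response differed (edgeR) in orange and the line of equal change. The thin band near 0 on the SMB56 axis reflects a table selected on that outcome.

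Under DMSO, SMB56-shSufu had more Gli1 and Ptch1 mRNA than SMB56 with TMM scaling, and less with mitochondrial scaling. Gli1 was 1.46-fold higher (0.55 ± 0.11, edgeR adjusted p 0.0016; -0.76 under mitochondrial scaling and -0.10 on FPKM) and Ptch1 1.501-fold (0.59 ± 0.09, edgeR adjusted p 0.00023; -0.76 under mitochondrial scaling). Gli2 was higher (1.22 ± 0.15, edgeR adjusted p 5.8e-05; -0.15 under mitochondrial scaling), and the cyclin gene Ccnd2 was lower (-1.49 ± 0.09, edgeR adjusted p 5.1e-07). Mycn (-0.19 ± 0.10, edgeR adjusted p 0.12) and Cdk7 (0.074 ± 0.09, edgeR adjusted p 0.50) did not pass, though Cdk7 was called lower under mitochondrial scaling (-1.25) and higher on FPKM (0.32). In the fit of its own groups Ccnd1 did not pass (0.05 ± 0.16, edgeR adjusted p 0.81) and Smo was lower (-0.37 ± 0.08, edgeR adjusted p 0.017). Myc was 3.25-fold higher (1.70 ± 0.09, edgeR adjusted p 4.0e-07) and Ddit4 was lower (-1.93 ± 0.09, edgeR adjusted p 1.9e-07).

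The highest folds were in Lsp1 (3.63 ± 0.19, edgeR adjusted p 4.0e-07), Cdkn1a (3.01 ± 0.17, edgeR adjusted p 5.7e-07), the filamin gene Flnc (2.78 ± 0.12), the taurine transporter gene Slc6a6 (2.63), Mras (2.63), Mfng (2.47), Sned1 (2.37) and Zim1 (2.25 ± 0.17). The lower genes of largest fold included Pcp4 (-4.85 ± 0.20, edgeR adjusted p 1.5e-07), the AMPA receptor gene Gria2 (-2.995 ± 0.21), Trnp1 (-2.88 ± 0.14), the cerebellin gene Cbln4 (-2.80 ± 0.14), the synaptic vesicle gene Synpr (-2.80 ± 0.28) and the histamine receptor gene Hrh3 (-2.58 ± 0.19). Lars2, its reads of uncertain source, was lower (-2.90 ± 0.13).

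Mitosis genes were higher in SMB56-shSufu, 18 of 21 with 0 lower (median 0.53, below 0 under mitochondrial scaling; camera adjusted p 2.8e-05, adjusted p = 0.38 with an estimated correlation). Nusap1 (0.77 ± 0.07, edgeR adjusted p 1.1e-05) and Ccna2 (0.95 ± 0.10) were higher, both below 0 under mitochondrial scaling. Replication and E2F genes were higher, 16 of 22 with 0 lower (median 0.38, below 0 under mitochondrial scaling; camera adjusted p 0.00027, adjusted p = 0.21 with an estimated correlation). So were Ccne1 (1.07 ± 0.11, edgeR adjusted p 1.7e-05) and E2f8 (0.87 ± 0.09), both below 0 under mitochondrial scaling. Granule neuron progenitor genes were lower, 7 of 11 with 1 higher (median -0.33, camera adjusted p 0.00010, adjusted p = 0.21 with an estimated correlation). Barhl2 (-2.42 ± 0.12, edgeR adjusted p 3.4e-07) and Sox4 (-1.66 ± 0.09) were lower and Lhx9 higher (1.30 ± 0.22, edgeR adjusted p 0.00048; below 0 under mitochondrial scaling). Neuronal differentiation genes were lower, 7 of 11 with 0 higher (median -0.55, camera adjusted p 0.010, adjusted p = 0.38 with an estimated correlation), such as Rbfox3 (-2.08 ± 0.16, edgeR adjusted p 3.0e-06) and Elavl3 (-1.32 ± 0.13, edgeR adjusted p 1.8e-05). Mitochondrially encoded genes were higher, 7 of 12 with 1 lower (median 1.15, camera adjusted p 0.0027, adjusted p = 0.56 with an estimated correlation). Their median was below 0 only under mitochondrial scaling, which is set by these same genes. The camera call was lost without SMB56 DMSO replicate 1, where the median stood 1.14 above that of other genes. mt-Co1 was higher (1.48 ± 0.14, edgeR adjusted p 1.3e-05) and mt-Nd3 lower (-1.67 ± 0.29, edgeR adjusted p 0.00061). Hedgehog targets had 4 higher and 2 lower (adjusted over the list alone, 4 and 3), with a median of -0.12, a mean of 0.07 and a camera direction of up (camera adjusted p 0.78), while neural stem and glia genes had a median of 0.10 and a mean of -0.04. Adjusted over the list alone, higher and lower counts were 3 and 3 for immediate early genes, 25 and 18 for ribosomal proteins and 55 and 39 for Zfp genes. They were 9 and 12 for OXPHOS and 12 and 5 for the proteasome. Camera called none of these lists.

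The lines differed in 3996 of 7244 genes, 1995 higher and 2001 lower in SMB56-shSufu, of which 556 by at least 2-fold (198 and 358). The fit of its own groups called 3948 of 9719 genes, 3021 of them among the 7244, with a common biological coefficient of variation of 11.3% against 8.62%. The split was 1531 and 2496 with library size, 876 and 2287 with ribosomal protein scaling and 21 and 6940 with mitochondrial scaling. A single knockdown line was compared with its parent, in libraries sequenced to other depths, so Sufu cannot be singled out as the source of these differences.

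THZ1 and GDC-0449 gave different profiles in SMB56. Gli1 was higher with THZ1 than with GDC-0449 (1.53 ± 0.14, edgeR adjusted p 2.0e-06, n = 2), as were Ptch1 (2.06 ± 0.09, edgeR adjusted p 1.6e-08), Mycn (1.67 ± 0.10, edgeR adjusted p 9.9e-08) and Sufu (1.42 ± 0.08, edgeR adjusted p 7.3e-08). Sox9 was higher with THZ1 (2.34 ± 0.12, edgeR adjusted p 2.7e-08), and Mcm10 (-1.61 ± 0.10, edgeR adjusted p 1.0e-07) and the neuronal RNA-binding protein gene Elavl4 (-2.29 ± 0.18, edgeR adjusted p 6.6e-07) were lower. Cdk7 had a difference of 0.00069 ± 0.09 (edgeR adjusted p 0.99) under TMM. It was called lower with THZ1 under library size (-0.62), upper-quartile (-0.34), authors' (-0.33), mitochondrial (-1.39) and ribosomal protein scaling (-0.96) and on FPKM (-0.77).

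Between the compounds, ribosomal protein genes were higher with THZ1, 69 of 71 with 0 lower (median 0.93, camera adjusted p 1.1e-08, adjusted p = 0.59 with an estimated correlation), with Rplp0 at 1.49 ± 0.10 (edgeR adjusted p 2.0e-07). The list median was below 0 under mitochondrial scaling, and also under ribosomal protein scaling, which is set by these same genes. Hypoxia and glycolysis genes were higher too, 9 with 1 lower (median 1.11, camera adjusted p 0.014, adjusted p = 0.59 with an estimated correlation). Their median was below 0 under mitochondrial scaling. All 12 mitochondrially encoded genes were higher (median 1.27, camera adjusted p 0.019, adjusted p = 0.59 with an estimated correlation). That median was below 0 only under mitochondrial scaling, which is set by these same genes. Transcription CDKs and TFIIH had 8 higher and 3 lower (median 0.68, below 0 under mitochondrial and ribosomal protein scaling; camera adjusted p 0.039, adjusted p = 0.59 with an estimated correlation), with Polr2a at 2.73 ± 0.10 (edgeR adjusted p 6.1e-09). That call was lost with library size (camera adjusted p 0.0941), mitochondrial scaling (0.109) and without GDC-0449 replicate 2 (0.0545). Mitosis genes were lower, 15 with 1 higher (median -0.49, camera adjusted p 0.014, adjusted p = 0.59 with an estimated correlation; camera adjusted p 0.0654 under mitochondrial scaling). Repair genes (14 lower, median -0.69, camera adjusted p 0.037, adjusted p = 0.61 with an estimated correlation) and Zfp genes (126 lower and 42 higher, median -0.69, camera adjusted p 0.014, adjusted p = 0.59 with an estimated correlation) were lower. Hedgehog targets had 5 higher and 3 lower (median 1.09, below 0 under mitochondrial scaling; camera adjusted p 0.13). Counts adjusted over the list alone differed only for the stress response (6 higher and 2 lower).

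The compounds differed in 5969 of 7244 genes, 2676 higher and 3293 lower with THZ1, of which 2710 by at least 2-fold (1373 and 1337). Those genes, too, come through the table selected on the THZ1 outcome in SMB56, so the share does not hold for all genes. The split was 1685 and 4640 with library size, 717 and 4934 with ribosomal protein scaling, 228 and 5705 with mitochondrial scaling, and 1057 and 4742 on FPKM. Folds of the compounds against their shared DMSO libraries had a correlation of 0.0549 (Spearman rho 0.0198), 51.3% with the same sign. Simulated data with no change but the same shared control gave a correlation of 0.441 (0.409 to 0.467) and 64.9%. The simulated folds held only spread between libraries. That correlation and share therefore cannot be set against data in which THZ1 changed many genes. The simulated covariance was 0.00304, against 0.0138 observed. The DMSO libraries were not split to give each compound its own control. Called with both compounds were 18 genes higher (13.5 expected) and 77 lower (48.9), with 15 (38.0) and 15 (17.4) in opposite directions. These expected numbers assume independent comparisons and leave out the shared DMSO libraries.

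The authors' deposited calls took in all but 8 genes of the table for THZ1 in SMB56 (4503 higher and 5496 lower with treatment). They numbered 1399 for GDC-0449 (448 and 951) and 6771 for THZ1 in SMB56-shSufu (2714 and 4057). Of those tested here, 5867 of 7238, 143 of 1153 and 5003 of 5120 were called here with the same sign, and 12, 0 and 0 with the opposite sign. The fits of own groups called 9808, 1398 and 6476 of the authors' genes with the same sign. The median fold here minus the authors' was 0.350, 0.024 and 0.233. Adjusted over the 20366 tests implied by the deposited p-values, 5592 genes were called for THZ1 in SMB56.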

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

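The tests on Sufu and the test of Lars2 against mt-Rnr2 were chosen only after the results were seen, and the search for sequence shared by Lars2 and Gm26917 was chosen before. The response to THZ1 differed between the lines for 1828 genes. Given as the log2 fold in SMB56-shSufu minus that in SMB56, hedgehog genes reported among them were Sufu (1.05), Gli1 (1.05), Gpr161 (0.72) and Kif7 (0.71), and pathway components had a median of 0.43. The hedgehog target list, with 3 members higher and 1 lower, was not called (median 0.15, camera adjusted p 0.25). Transcription genes were Polr2a (-0.96) and Gtf2h1 (-0.93), with a median of -0.28 for transcription CDKs and TFIIH. Ribosomal protein genes had a median of -0.67, with Rpl17 at -1.38 and Rps6 at -1.16. Other genes with a positive difference were Lars2 (2.28), Gnb1l (2.11), Ksr1 (2.03), Rtn4r (1.76), Mgat3 (1.73) and Atoh1 (0.66), and with a negative difference Pcp4 (-4.99), Pkn3 (-2.34), Zdhhc12 (-1.92), Isoc2a (-1.58) and Znrd1as (-1.51).

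Sufu rose with THZ1 by more in the line that carries the hairpin against it. A weaker knockdown under THZ1 could not raise Sufu above its level in SMB56 with THZ1, and Sufu in SMB56-shSufu stayed below that level under TMM (-0.479 ± 0.079, log2). That gap was not computed under other scalings, and ribosomal protein scaling gave a larger difference of responses (1.71 ± 0.18). The explanation was thus not excluded and remains open, and the narrower gap between the lines is the pattern itself and no evidence for it. A scaling effect would shrink the difference under some other scaling, but the lowest difference was 0.959 ± 0.113, with RLE, so none of the scalings tried accounts for it. They moved the median difference of all genes by only -0.093 to 0.67 from TMM, so none could have taken 1.05 to 0. A larger scaling difference between the lines was not tested, since no spike-in was used. A hairpin-specific assay or another hairpin would separate a weaker knockdown from a larger response of the Sufu gene.

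Lars2 and Gm26917 were far higher with THZ1 in both lines. If all reads assigned to Lars2 had come from the mitochondrial ribosomal RNA mt-Rnr2, both would move by the same amount. Lars2 minus mt-Rnr2 was 2.84 ± 0.21 in SMB56 and 5.44 ± 0.22 in SMB56-shSufu, which argues against mt-Rnr2 as the only source. A mix with reads of Lars2 itself need not give equal folds, so the difference cannot exclude a part from mt-Rnr2. Lars2 and mt-Rnr2 share 0 words of 31 bases. If Lars2 and Gm26917 took the same reads through shared sequence, their models would share words, and they shared 0. In the fit of its own groups, Mir6236, another of the ribosomal RNA-like genes, also rose with THZ1 in SMB56-shSufu (5.95 ± 0.20), from 7.14 to 442 CPM. Lars2 and the gene model Gm15564 share 22 such words, found only after the result. Sequences outside the ribosomal RNA-like gene models were not searched, so an RNA not listed among the genes could still feed Lars2, and this remains open. Mapping the reads with ribosomal RNA sequences included would settle it.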

How the results depend on the processing

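With 2 libraries per group, tests rest on 5 residual degrees of freedom pooled over all groups, and replicate numbers were not treated as pairs, since the labels do not say that they are. Deviations of equally numbered libraries had correlations of -0.108 to 0.145 over all pairs of groups, and of 0.00095 to 0.145 within a line. Blocking on the replicate number gave 264 genes for GDC-0449 (89 higher and 175 lower, 144 shared with the 145) and changed no other count by more than 1.5 times. Of the values repeated under each setting, 4728 for genes stayed the same, 211 were weaker, 27 stronger and 89 reversed. For lists 646 stayed the same, 56 were weaker and 0 reversed, and for counts and correlations 247 stayed and 61 moved. Unless said otherwise, the cause was not tested for any value that moved or reversed. Scaling by mitochondrial genes moves the folds of a comparison together, and this is by construction, since the mitochondrial share differed with THZ1 and between the lines. The fit with the authors' size factors was not run for the comparison of the lines, since the authors scaled each table alone. Without ribosomal RNA-like and mitochondrial genes, an alternative added after seeing the data, 5782, 146, 5907, 1834, 3989 and 5911 genes were called in the 6 comparisons, of which 5771, 142, 5891, 1755, 3837 and 5897 were shared.

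Counts moved as follows, with the cause of each move not tested. For GDC-0449, though, the simulation had shown the pooled spread to make the test conservative, so its count of 145 is likely too low. For THZ1 in SMB56, 9813 of 9863 genes were called with its own groups and 2699 at 2-fold, and 0 lists with an estimated correlation and 17 with fry against 9. For GDC-0449, 42 genes were called with mitochondrial and 42 with ribosomal protein scaling, 3633 of 10008 with its own groups and 241 with DESeq2. They were 2364 with voom quality weights (added after seeing the data), 51 on FPKM with a pseudocount of 1, 45 with 0.1 and 51 for FPKM of at least 1 in 2 libraries. Also for GDC-0449, they were 35 at 2-fold, 54 at an edgeR adjusted p under 0.01, 35 to 941 with a library left out, 1142 at an unadjusted p under 0.05, and 2 lists with an estimated correlation and 4 with fry against 9. Fry, which tests a list against no change where camera tests it against other genes, did not pass there for repair (fry adjusted p 0.195), hypoxia (0.110), neuronal differentiation (0.0551), mitochondrially encoded (0.159) and Zfp genes (0.217), which camera called. For THZ1 in SMB56-shSufu, 2438 genes were called at 2-fold, and 0 lists with an estimated correlation and 13 with fry against 6. For the difference of THZ1 effects, 93 genes were called with mitochondrial and 4550 with ribosomal protein scaling, 921 and 907 on FPKM with pseudocounts of 1 and 0.1, 921 for FPKM of at least 1 in 2 libraries, 228 at 2-fold, 744 at an edgeR adjusted p under 0.01 and 869 to 2985 with a library left out. Lists there were 0 with an estimated correlation, 5 with fry and 3 to 6 with a library left out. For the lines, 6961 genes were called with mitochondrial scaling and 556 at 2-fold, and 0 lists with an estimated correlation and 10 with fry against 5. For THZ1 against GDC-0449, 2710 genes were called at 2-fold, and 0 lists with an estimated correlation and 17 with fry against 7. The correlation of THZ1 folds between the lines was 0.907 over 6591 genes of at least 10 CPM, and 0.881 to 0.908 over all 7244 genes with a library left out. That of THZ1 and GDC-0449 folds was 0.0832 over 6675 genes of at least 10 CPM, and 0.0445 to 0.0928 over all 7244 with a library left out, the last without SMB56 DMSO replicate 2.

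Of named genes called for GDC-0449, 17 of 26 lost the call with some library left out (edgeR adjusted p 0.0519 to 0.330), and Gli1, Ptch1, Hpca, Adamts14, Tbata, Lrp8, Rgma, Prm1 and Sox9 kept it. For the difference of THZ1 effects 3 of 19 lost it: Kif7 (0.0579 to 0.116), Rtn4r (0.0509 to 0.0734) and Znrd1as (0.0827 without SMB56 THZ1 replicate 1). No named gene lost its call in the other comparisons. For GDC-0449, the fit of its own groups called all 15 genes named for their large folds. The common biological coefficient of variation was 2.27% in that fit and 8.62% in the main fit.

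Directions reversed as follows, with the cause not tested beyond the shift in scale. Under mitochondrial scaling for THZ1 in SMB56 the values were Ptch1 -0.75, Sufu -0.36, Mycn -0.51, Cdk7 -1.47, Rps15a -0.24, Myc -0.019, Vegfa -0.16, Aurka -0.89, Mcm7 -0.91, Pkm -0.22, Zic1 -0.018, Rplp0 -0.017 and Atoh1 -0.093. For GDC-0449: Cdk7 -0.073. For THZ1 in SMB56-shSufu: Ptch1 -0.55, Mycn -0.31, Cdk7 -1.35, Supt5 -0.028 and Mki67 -0.86. For the lines: Ptch1 -0.76, Gli1 -0.76, Cdk7 -1.25, Ccne1 -0.27, Lhx9 -0.088, Nusap1 -0.58, Ccna2 -0.36, E2f8 -0.48 and Gli2 -0.15. For THZ1 against GDC-0449: Cdk7 -1.39. Under ribosomal protein scaling, for THZ1 in SMB56: Ptch1 -0.18, Cdk7 -0.89, Aurka -0.32 and Mcm7 -0.34. In the other comparisons: Cdk7 -0.18 for THZ1 in SMB56-shSufu, Cdk7 -0.10 for the lines and Cdk7 -0.96 for THZ1 against GDC-0449.

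On FPKM with a pseudocount of 1, and the same for FPKM of at least 1 in 2 libraries: Ptch1 -0.37, Cdk7 -0.77, Rps15a -0.10, Aurka -0.18 and Mcm7 -0.076 for THZ1 in SMB56, Cdk7 -0.0032 for GDC-0449, Cdk7 -0.55 and Mki67 -0.13 for THZ1 in SMB56-shSufu, Gli1 -0.10 for the lines, and Cdk7 -0.77 for THZ1 against GDC-0449. With a pseudocount of 0.1: Ptch1 -0.39, Cdk7 -0.95, Rps15a -0.10, Aurka -0.18 and Mcm7 -0.076, then Cdk7 -0.0037, then Cdk7 -0.64 and Mki67 -0.13, then Gli1 -0.11, then Cdk7 -0.95, in the same order of comparisons. With library size: Cdk7 -0.56 and Mcm7 -0.0069 for THZ1 in SMB56, and Cdk7 -0.45 in SMB56-shSufu, -0.023 for the lines and -0.62 for THZ1 against GDC-0449. Cdk7, near 0 and not called with TMM over all libraries, also reversed in these fits, and for THZ1 in SMB56 it was called lower in those with library size, upper-quartile and authors' factors, mitochondrial and ribosomal protein scaling, own groups and FPKM. For THZ1 in SMB56, in SMB56-shSufu and against GDC-0449, Cdk7 was -0.26, -0.23 and -0.34 with upper-quartile and -0.30, -0.14 and -0.33 with the authors' factors (added after seeing the data). Cdk7 was -0.20 and -0.012 with own groups, -0.053 for the difference with RLE and -0.053 with DESeq2, and -8.6e-05 for THZ1 against GDC-0449 with the replicate block. With a library left out, Cdk7 was -0.019 for THZ1 in SMB56 and -0.069 against GDC-0449 without SMB56 THZ1 replicate 1, -0.0069 against GDC-0449 without GDC-0449 replicate 1, and 0.066 against GDC-0449 without SMB56 THZ1 replicate 2. For the difference, Cdk7 was -0.025 without SMB56 THZ1 replicate 2, -0.030 without SMB56-shSufu DMSO replicate 2, -0.035 without SMB56-shSufu THZ1 replicate 2 and 0.11 without SMB56-shSufu THZ1 replicate 1. Mycn was -0.0039 without SMB56-shSufu DMSO replicate 2 and 0.31 without SMB56-shSufu DMSO replicate 1.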

Other observations

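The prediction for gene span and exon number was written before its test was run. Exon number is that of a gene's longest annotated transcript. The comparison of genes whose longest transcript has 1 exon was chosen only after the results were seen, with no test of the difference made. There were 517 such genes, which may also have shorter transcripts of more exons. In SMB56, 264 were higher and 177 lower, with a median of 0.60 against -0.24 for other genes. In SMB56-shSufu, 233 were higher and 174 lower, with a median of 0.18 against -0.12. Sox9, a transcription factor of neural stem cells and glia, and Prm1, a protamine gene, moved in opposite directions with the compounds under TMM. Sox9 rose with THZ1 (0.96 ± 0.11) and fell with GDC-0449 (-1.38 ± 0.11). Mitochondrial scaling shifts THZ1 folds in SMB56 by -1.51 at the median, more than the size of that rise. Prm1 rose with THZ1 (2.13 ± 0.15, edgeR adjusted p 2.1e-07) and fell with GDC-0449 (-1.56 ± 0.17).

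THZ1 lowered some genes and raised others in both lines. As a hypothesis, blocked elongation could lower long genes with many exons more than short ones, which predicts a Spearman rho of -0.2 or below between fold and gene span or exon number in both lines. For gene span rho was 0.0522 in SMB56 and 0.135 in SMB56-shSufu, and for exon number it was -0.0144 and 0.0474 (SE 0.0118), over 7237 of 7244 genes. The SE takes genes as independent, which they are not, so it gives only a scale. These genes come through a table selected on the SMB56 THZ1 outcome, so rho may differ over all genes. Given the mean level, an adjustment that the prediction did not name, rho for exon number was -0.143 and -0.0725 and for gene span -0.0158 and 0.0851. Exon number then had a weak negative relation to the fold, and none of these values reached the predicted -0.2. Transcript length gave 0.103 in SMB56 and 0.222 in SMB56-shSufu.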
